A study of Mus musculus with 2 samples.

How the data were processed

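Cells came from the cervical loop region of incisors of 1 control mouse and 1 mouse with Memo1 removed by K14-driven Cre, both at postnatal day 20, and each mouse gave 1 droplet library (10x Genomics). Tissue was digested with trypsin and dispase, and about 10000 cells were loaded. Per the labels, the authors aligned reads to mm10 and made UMI counts per gene and cell with Cell Ranger, whose version is not given, and processed them with Seurat 3. The deposited values were whole-number counts for 19626 genes in 23528 cells. Each cell came with the authors' cluster number, for all cells and again within the ameloblast lineage. How the lineage was picked is not stated, and the clusters carried no cell type names. In the file, cells held 501 to 49967 UMIs, at least 200 genes and at most 30.0% mitochondrial counts, and cells outside those limits are absent. The 4 columns with plotting coordinates were not used.

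The control library held 79518656 UMIs in 9708 cells and the mutant library 120862385 UMIs in 13820 cells. Below 1000 UMIs lay 28.8% of the control and 21.7% of the mutant cells. Amelx alone took 5.93% of the control and 4.20% of the mutant counts, and haemoglobin 3.04% and 1.47%. For 18882 gene symbols a position was found in GENCODE M21 (GRCm38).

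Clusters were joined into classes and named by the authors' numbers plus marker genes fixed in advance. A name needed at least 3 markers 1.5-fold above the other clusters and a mean log2 fold of at least 1, and these limits were set after the data had been seen. A class was compared when both libraries had at least 50 cells in it, which left 26 classes, 8 of the lineage and 18 others. In 3 further classes there were fewer cells. Counts were summed over the cells of a class in each library and divided by the class total, giving CPM. Ratios are mutant over control unless given as fold lower, which is control over mutant, with exact 95% conditional intervals of 2 Poisson counts and Clopper-Pearson intervals for shares. With 1 library per group there is no estimate of variation between mice, so no p-values were computed. Members of a list are counted as higher or lower where their counting interval excludes 1. The maturation class held 2315741 and 1162618 counts, and the secretory class 7682145 and 9155912.

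Genes were named by a fixed rule. In each class, genes with at least 50 CPM in the higher library and at least 50 counts in all were ordered by how far the nearer bound of the interval lay from 1. The first 10 higher and first 10 lower could be named, up to 5 each outside the lineage, with up to 4 members of each list and Memo1. Xist, Tsix, Y-linked, mitochondrial, ribosomal protein and haemoglobin genes were not eligible by rank. Genes with 0 counts in 1 library are given against a floor of 3 counts, and get no ratio where the other library does not exceed that floor. Some genes that the rule allows are not reported here. The 10 leading genes of a cluster are those with at least 50 CPM that stand farthest above the other clusters after 10 CPM is added to both, and those that differ are pointed out because they define the cluster. Shares were compared for the whole lineage and for classes in which 0 leading genes had an interval wholly beyond 2-fold between libraries, a rule set after the data had been seen.

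There were 33 lists of gene functions and 27 lists of cell type markers with 553 genes, of which 15 were not in the file. A list was measured on members with at least 10 CPM on average and 20 counts, and needed 3 of them. Its median was placed among 10000 random lists drawn from the 200 genes nearest in expression to each member. The groups, main analysis, lists of alternatives and rule for naming genes were fixed before the data were examined, but the limits for naming classes were not. Alternatives were TMM factors from edgeR 4.0.16, median-of-ratios factors from DESeq2 1.42.0, totals without the most abundant transcripts, and stricter cell limits (1000 UMIs, 500 genes, 10% mitochondrial counts). Others were cells thinned to 1000 UMIs, means of per-cell CPM, leaving out the 5% of cells with the most UMIs, and classes by marker score.

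The intervals and lists were tested on simulated data, with Poisson counts drawn around the mean profile of both libraries at the depth of the class, so variation between cells or mice was not simulated. Among genes left alone in the maturation class the intervals held the true ratio for 96.0%, and among altered genes for 90% to 98%. Of genes raised 2-fold 96% were recovered. The intervals excluded 1 for 29.2% of the genes left alone, because the altered genes shift the class total. Of 400 random lists 6.5% fell outside the central 95%, and 20 of 20 altered lists did. In the secretory class the intervals held 95.7%, excluded 1 for 8.9%, and 5.0% of random lists fell outside. Doublets were not called. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.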

Results

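The incisor of the mouse grows throughout life, so the enamel organ along its length holds every stage of the ameloblast. Ameloblasts are the epithelial cells that make enamel. Single-cell RNA sequencing with 10x Genomics droplets was done on cells from the cervical loop region of incisors taken at postnatal day 20. One library came from 1 control mouse and 1 library from 1 mouse in which K14-driven Cre removes Memo1 from epithelium. The control library held 9708 cells with 79518656 UMIs in total and a median of 2643 UMIs per cell. The mutant library held 13820 cells with 120862385 UMIs and a median of 6798 per cell. The depositors had called 2981 control and 2303 mutant cells ameloblast lineage and had numbered the clusters without naming them. There were no replicates, so no test between groups was possible and "higher" and "lower" below describe these 2 libraries. All intervals are 95% and cover counting error only.

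Memo1, the targeted gene (chromosome 17, 74199036 to 74295521, minus strand, GRCm38 with GENCODE M21), was sequenced at like levels in both libraries. Over all cells it gave 19.0 CPM in the control and 17.7 CPM in the mutant, where CPM is a gene's counts scaled to the total counts of the same cells. In the lineage the ratio of mutant to control was 0.693 (0.480 to 0.984) in cluster 2. In the secretory ameloblast-like class it was 1.09 (0.839 to 1.43) and in the maturation ameloblast-like class 1.21 (0.686 to 2.08). It was 0.596 (0.264 to 1.26) in the preameloblast-like class. Averaging each cell's CPM instead of summing counts put the last 2 at 0.495 and 2.15, so these Memo1 ratios are loose. Endothelial cells, outside the Cre domain, gave 21.8 and 23.7 CPM. Reads from outside the deleted part of the gene are counted too and the labels do not say which part is deleted, so these levels do not check the deletion.

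The first comparison asks about the title question of the series, the role of MEMO1 in the maturation of ameloblasts. Over all cells that the depositors had called ameloblast lineage, without splitting them by cluster, transcripts of maturation ameloblasts were much scarcer in the mutant library. Transcripts of secretory ameloblasts were not. How the lineage was picked is not stated, so this comparison too may depend on clusters. The control lineage had 1.64 maturation marker counts per 100 secretory marker counts and the mutant lineage 0.119, a 13.7-fold lower ratio (13.4 to 14.1). Odam, a protein of the basal lamina that maturing ameloblasts lay on enamel, was at 1151 CPM in the control lineage and 19.9 CPM in the mutant, 58.0-fold lower (53 to 63.6). Klk4, the protease that clears enamel matrix during maturation, was 8.26-fold lower (7.57 to 9.02). Amtn, a second basal lamina protein, was 6.01-fold lower (5.84 to 6.18). One mutant cell of the maturation class held 44.5% of the Odam counts of the mutant lineage, and without it Odam was 104-fold lower (92.5 to 118), Klk4 14.4-fold (12.9 to 16.2) and the ratio of marker counts 19.3-fold (18.7 to 19.9).

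Other maturation markers had the same direction. Wdr72, whose loss in people causes soft enamel, was 16.0-fold lower (9.23 to 30.5) and Slc24a4, a calcium exporter of ameloblasts, 7.48-fold lower (6.15 to 9.18). Slc34a2, a phosphate carrier, was closer in both libraries, at 13.6 CPM and 10.5 CPM. The secretory transcripts Enam, Mmp20 and Amelx were higher in the mutant lineage, by 1.81-fold (1.79 to 1.82), 1.60-fold (1.57 to 1.63) and 1.43-fold (1.43 to 1.43), and Ambn by 1.07-fold (1.07 to 1.07). Odam (5:87885029 to 87894174), Amtn (5:88376108 to 88385916), Ambn (5:88455991 to 88468531) and Enam (5:88487975 to 88506049) lie close together on the plus strand of chromosome 5.

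**Figure D1:**
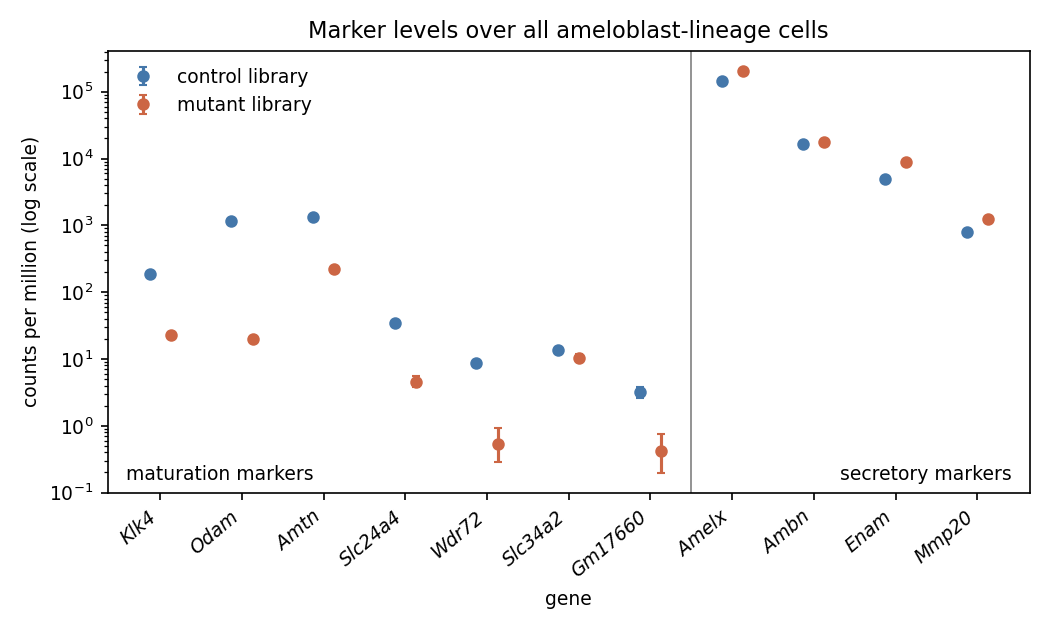
Levels in CPM (log axis) of the maturation and secretory ameloblast markers over all lineage cells of the control and mutant libraries, with 95% counting intervals. Odam sits at 1151 CPM in the control and 19.9 CPM in the mutant, while Amelx, Enam and Mmp20 are higher in the mutant.

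Ameloblast-lineage cells made up 30.7% of the control cells (29.8 to 31.6, exact Clopper-Pearson) and 16.7% of the mutant cells (16.0 to 17.3). Among cells with at least 1000 UMIs the shares were 34.0% and 14.6%. By the fixed markers, clusters of the lineage were named secretory ameloblast-like (223 control and 286 mutant cells), maturation ameloblast-like (187 and 78), preameloblast-like (227 and 223), stratum intermedium or papillary layer-like (211 and 174) and outer enamel epithelium or stellate reticulum-like (495 and 166). Clusters 0, 2 and 6 could not be named by these markers. Since the clusters rest partly on genes that differ between the libraries, the sizes of lineage classes are given without a direction. Outside the lineage, dental pulp mesenchyme-like cells of cluster 5 were 0.948% of the control cells (0.765 to 1.16) and 9.78% of the mutant cells (9.29 to 10.3). Macrophage or monocyte-like cells were 5.06% (4.63 to 5.51) and 7.14% (6.72 to 7.58), and cycling cells 4.83% (4.41 to 5.28) and 2.00% (1.77 to 2.24).

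Within the maturation ameloblast-like class, cells of the mutant library had lower levels of most late enamel genes. Of 4 measured proteases and late matrix genes 3 were lower and Mmp20 higher (median -2.20, percentile 0.01), and of 3 enamel matrix genes Enam and Amelx were higher and Ambn lower. Odam was 39.6-fold lower (36.1 to 43.5), Klk4 5.42-fold lower (4.97 to 5.93) and Amtn 3.90-fold lower (3.79 to 4.01) than in the control class. These genes, with Car6, Slc24a4, Car2 and Fth1, are among the 10 that define the class, so their differences also reflect which cells the clustering put there. Of those 10 genes 9 differed beyond 2-fold, so the class may hold different cells in each library. In endothelium Odam was at 11.8 CPM in the control and 0 counts in the mutant, against 15808 CPM and 399 CPM here. The mutant cell with the most Odam held 46.1% of the Odam, 43.4% of the Klk4 and 28.1% of the Amtn counts of its class. Without it Odam was 70.7-fold lower (62.4 to 80.4), Klk4 9.21-fold (8.21 to 10.3) and Amtn 5.22-fold (5.04 to 5.39). No control cell was left out, so these larger folds were largely fixed in advance. The class held 2315741 control and 1162618 mutant counts.

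Several genes that do not define the class were lower still. Clu, a secreted chaperone, was at 6353 CPM in the control and 52.5 CPM in the mutant, 121-fold lower (94.2 to 158) and below its level in endothelium (292 CPM and 296 CPM). Cryaa, a small heat-shock protein, was at 141 CPM in the control and had 0 counts in the mutant, at least 54.7-fold lower. Cldn1, a tight junction protein, was 37.4-fold lower (25 to 58.5). The mutant cell with the most Odam also held 62.5% of the Cldn1 and 41.0% of the Clu counts, and without it Cldn1 was 95.8-fold (50.4 to 210) and Clu 197-fold lower (142 to 282). Wdr72 was 24.6-fold lower (10.4 to 76.4), with all 5 mutant counts in that cell and so at least 39.4-fold lower without it. Fgfr1, a receptor for fibroblast growth factors, was 18.7-fold lower (11.9 to 31.3). Plb1, Slc34a2, Adora2b and Lyn had 1 or 2 counts in the mutant. Plb1, a phospholipase, was 145-fold lower (39.9 to 1199), Slc34a2 137-fold (24.3 to 5413), the adenosine receptor Adora2b 108-fold (19.2 to 4283) and the kinase Lyn 96.4-fold (17.1 to 3827). Fxyd4, a regulator of the sodium pump, was 50.6-fold lower (19.6 to 187). Some genes that other lineage cells also express did not follow, or followed far less, over the whole lineage. There, without the mutant cell with the most Odam, control over mutant was 0.773 (0.767 to 0.780) for Clu, 1.09 (1.04 to 1.15) for Fgfr1, 1.07 (0.934 to 1.22) for Cftr and 1.85 (1.75 to 1.94) for Cldn1, so their folds within the class may rest on which cells it holds.

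Higher in the mutant class were Hpgd, which breaks down prostaglandins, at 6.48 CPM and 249 CPM (38.4-fold, 22.9 to 69.5), and Angptl1, a secreted angiopoietin-like protein (9-fold, 5.98 to 14). Smpdl3a was 5.91-fold higher (5.18 to 6.76), Srpx 6.20-fold (4.39 to 8.92) and Ggct 6.51-fold (4.28 to 10.1). Dcn, a fibroblast proteoglycan, was 10.7-fold higher (5.56 to 22.6), with 72.9% of its mutant counts in 1 cell. Csn3 was 30.3-fold higher (20.3 to 46.9) and Btbd3 5.76-fold higher (4.53 to 7.38). Csn3 was lower in the mutant, at a ratio of 0.494, once the 5% of cells with the most UMIs were left out. Btbd3 was lower, at 0.839, after cells were thinned to 1000 UMIs, which left out 41 control and 20 mutant cells.

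**Figure D2:**
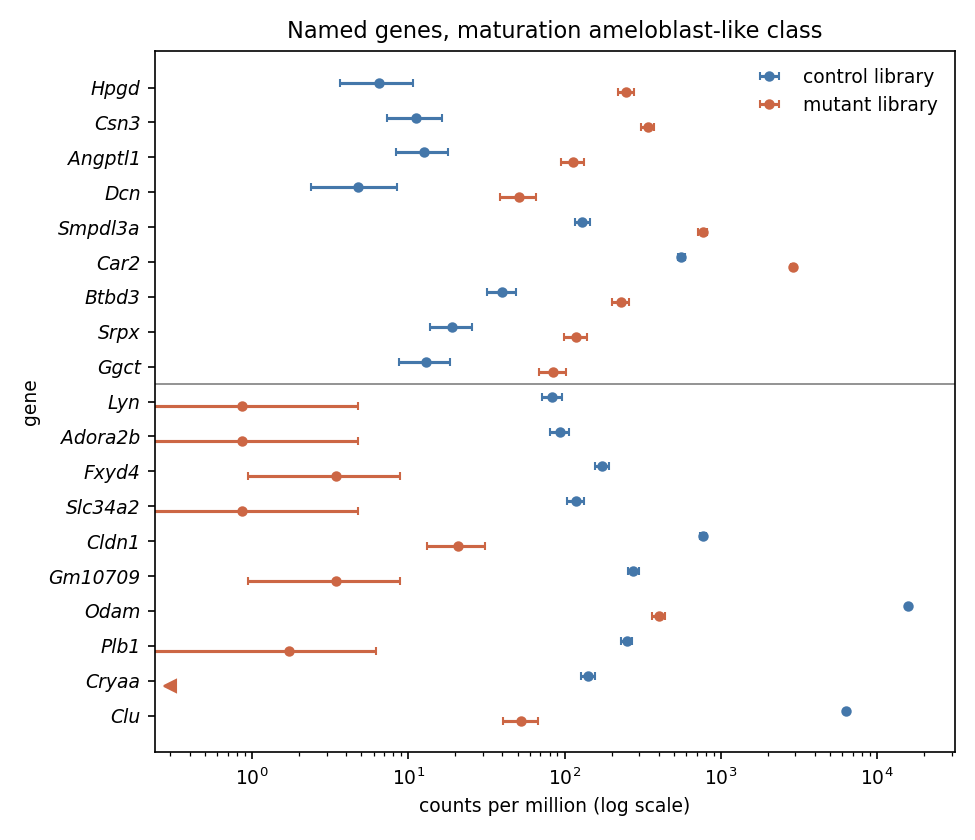
Levels in CPM (log axis) of genes named in the maturation ameloblast-like class of the control library (187 cells) and the mutant library (78 cells), with 95% counting intervals and a triangle at the left edge for 0 counts. Clu is at 6353 CPM in the control and 52.5 CPM in the mutant, and Hpgd at 6.48 CPM and 249 CPM.

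By gene groups fixed in advance, the transport functions of enamel maturation leaned to lower values in this class. Each median log2 ratio is placed among 10000 random lists of like expression, as a description of these libraries. Of 11 measured genes of bicarbonate, chloride and pH regulation, 8 were lower and 3 higher (median -0.83, percentile 0.07, mean -0.25). The chloride channel Cftr was 3.24-fold lower (2.45 to 4.36) and the secreted carbonic anhydrase Car6 2.55-fold lower (2.35 to 2.77), or 6.13-fold (5.42 to 6.96) without the mutant cell with the most Odam, which held 60.0% of its counts. Against that direction, the cytosolic carbonic anhydrase Car2 was 5.18-fold higher (4.86 to 5.53) and the bicarbonate carrier Slc4a4 2.61-fold higher (2.04 to 3.34). Of 13 genes of calcium and phosphate transport 8 were lower and 4 higher (median -0.96, percentile 0). The calcium pump Atp2b1 was 2.83-fold higher (2.58 to 3.10) and the calcium channel Itpr1 2.83-fold higher (2.45 to 3.27). Copper handling (4 of 6 lower, median -0.82, percentile 0.5) included the metallothioneins Mt2, 9.48-fold lower (4.88 to 21.1), and Mt1, 4.72-fold lower (4.04 to 5.53). Both were lower in endothelium too, Mt2 11.9-fold (6.82 to 22.2) and Mt1 2.76-fold (2.36 to 3.24), so this difference is not particular to the class. All 12 transcripts of the mitochondrial genome were lower (median -0.39, percentile 0.71).

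Signalling and regulatory genes went both ways. Targets and members of the BMP pathway were higher for 6 of 9 (median 0.99, percentile 100), with Id1 3.94-fold higher (3.46 to 4.49) and Bambi 3.22-fold higher (2.91 to 3.57), whereas the ligand Bmp7 was 3.12-fold lower (2.5 to 3.92). Among transcription factors of ameloblasts, Sp6 was 3.25-fold lower (2.36 to 4.58) and Runx2 2.07-fold lower (1.78 to 2.41), while Satb1 was 2.25-fold higher (1.95 to 2.59) and Runx1 1.92-fold higher (1.77 to 2.10). Of the enamel matrix genes, Enam was 2.75-fold higher (2.69 to 2.80), Amelx 1.56-fold higher (1.55 to 1.57) and Ambn 1.68-fold lower (1.66 to 1.70). ErbB and motility effectors of MEMO1 had a median of -0.04 (percentile 55.8), with 2 of 10 higher and 2 lower. Their medians in the other 7 lineage classes lay from 0.08 to 0.25.

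In secretory ameloblast-like cells, the main matrix genes were close in both libraries. Amelx was 1.03-fold lower (1.02 to 1.03), Ambn 1.35-fold lower (1.34 to 1.35) and Enam 1.25-fold higher (1.24 to 1.26). Cst6, an inhibitor of cysteine proteases and one of the genes that define the class, was at 13.3 CPM in the control and 385 CPM in the mutant, 29.0-fold higher (23.8 to 35.7), and 2.00-fold higher once the 5% of cells with the most UMIs were left out. Gnrh1, gonadotropin-releasing hormone, was 17.9-fold higher (15.1 to 21.4), with 62.1% of the control and 67.5% of the mutant counts in 1 cell each. Pitx1, a transcription factor of tooth epithelium, was 4.77-fold higher (3.89 to 5.91), Fabp5, a fatty acid carrier, 3.61-fold (3.08 to 4.26) and the tubulin Tubb6 3.21-fold (2.98 to 3.47). Sparc, a matrix protein abundant in endothelium (5712 CPM and 5625 CPM), was 4.80-fold higher (4.45 to 5.19).

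Lower in mutant secretory cells were Angptl7, a secreted angiopoietin-like protein (5.22-fold, 4.49 to 6.08), the calcium-binding protein Caln1 (4.27-fold, 3.54 to 5.18), Parvb, which links integrins to actin (2.85-fold, 2.47 to 3.30), Pdpn (2.73-fold, 2.29 to 3.27), Cox4i2 (2.77-fold, 2.41 to 3.19), Cpq (2.35-fold, 2.05 to 2.70) and Rnaset2a (3.48-fold, 3.19 to 3.80). Amtn was at 180 CPM and 2.73 CPM (25 mutant counts), 65.8-fold lower (44.4 to 102), with 52.5% of the control and 52.0% of the mutant counts in 1 cell each. Its level in endothelium was 15.4 CPM and 2.42 CPM, and it was named as lower in 5 of the 26 classes. Immediate early genes, which also answer to tissue dissociation, were higher for 11 of 13 (median 0.69, percentile 100). Jun was 3.29-fold higher (2.82 to 3.86) and Atf3 6.90-fold (4.77 to 10.3). Transcripts of dentin and bone matrix were higher for 4 of 5 (median 2.12, percentile 100), among them Col1a2, 4.34-fold (3.72 to 5.09; endothelium 25.2 CPM and 74.2 CPM), and those of macrophages for 3 of 3 (median 1.12). The median over all genes of this class was 0.12.

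**Figure D3:**
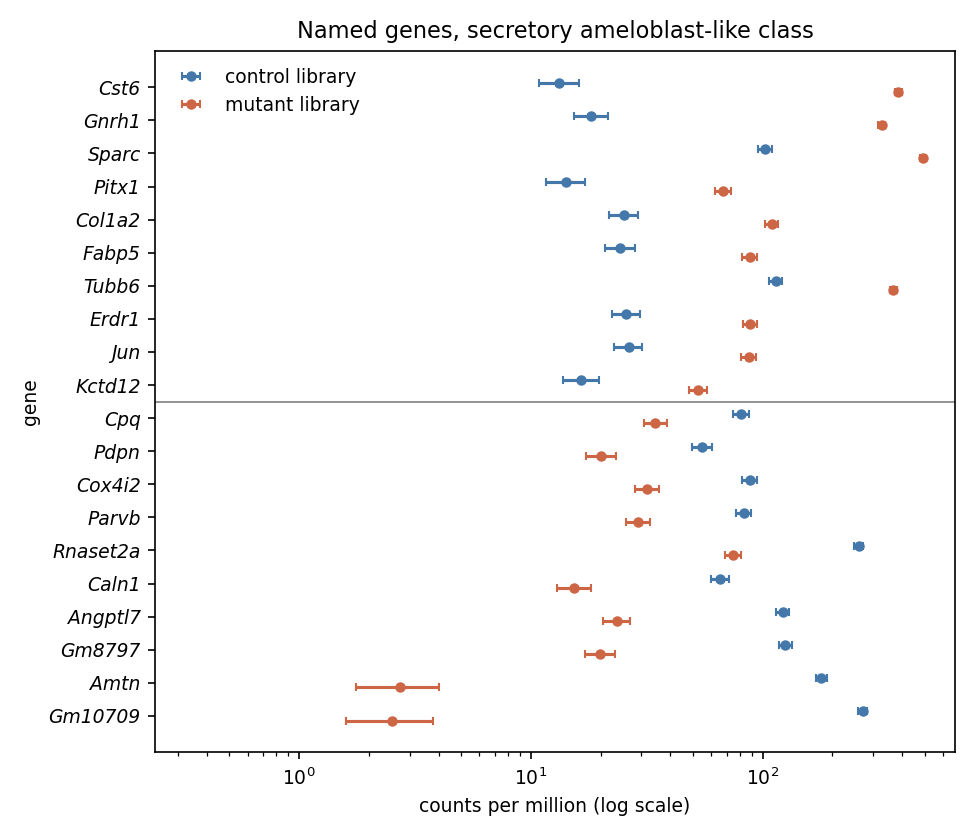
Levels in CPM (log axis) of the genes named in the secretory ameloblast-like class of the control library (223 cells) and the mutant library (286 cells), with 95% counting intervals. Cst6 is at 13.3 CPM in the control and 385 CPM in the mutant, and Angptl7 at 122 CPM and 23.5 CPM.

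Preameloblast-like cells of the mutant had lower levels of cell division transcripts. Of this class 62 of 227 control and 108 of 223 mutant cells had fewer than 1000 UMIs. Of the 10 genes that define it 4 differed, all of them haemoglobin transcripts, so it may hold different cells in each library. Genes of S phase were lower for 8 of 14 and higher for 0 (median -0.94, percentile 0), and genes of the G2 and M phases were lower for 4 of 5 (median -2.74, percentile 0). Uhrf1 was 4.61-fold lower (1.77 to 15.2) and Mki67, a marker of cycling cells, had 38 control and 2 mutant counts (14.6-fold lower, 3.77 to 125). Enam was 1.98-fold higher (1.84 to 2.14) and Mmp20, the secretory protease, 2.24-fold higher (1.88 to 2.68). The transcription factor En1 had 74 control and 0 mutant counts, 19.0-fold lower against the floor of 3 counts, and Barx2 was 4.08-fold lower (2.24 to 8.04). Haemoglobin transcripts were higher in this class (median 6.33, percentile 100), but they are among the genes that define it and 99.1% of the mutant Hbb-bs counts lay in 1 cell. They were lower in cluster 6 (median -3.93, percentile 0).

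Stratum intermedium or papillary layer-like cells, which lie behind the ameloblasts, had higher hedgehog and calcium genes in the mutant. Of 6 hedgehog genes 5 were higher (median 0.67, percentile 99.8), with Gli1, a target of the pathway, 2.03-fold (1.61 to 2.58) and the ligand Shh 1.55-fold (1.47 to 1.63). Of 11 genes of calcium and phosphate transport 9 were higher (median 0.56, percentile 99.9), with the phosphate carrier Slc20a1 at 1.95-fold (1.63 to 2.34). The thrombin receptor F2r was 8.03-fold higher (6.28 to 10.4), Cystm1 8-fold (5.37 to 12.3) and Nrp2, a semaphorin receptor, 4.37-fold (3.36 to 5.74). Immediate early genes were higher for 12 of 16 (median 1.05, percentile 100), with Fos 3.94-fold (3.29 to 4.74). The hair-type keratin Krt75 was 2.39-fold lower (1.91 to 3.02). The median over all genes of the class was 0.22.

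Cluster 2, an unnamed class of the lineage, had higher Notch genes (5 of 7, median 0.88, percentile 100) and p53 targets (6 of 9, median 0.85, percentile 100) in the mutant. Notch1 was 2.84-fold higher (2.42 to 3.34) and the cell cycle inhibitor Cdkn1a 5.27-fold (4.54 to 6.13). Genes of bicarbonate, chloride and pH regulation were higher for 7 of 10 (median 0.61, percentile 99.9), with Slc4a4 1.96-fold (1.86 to 2.06). The insulin-like growth factor binding proteins Igfbp5 and Igfbp2 were 3.18-fold lower (3.01 to 3.36) and 2.81-fold lower (2.67 to 2.96), and both help define this cluster. The bone genes Ibsp, Mmp13 and Spp1 were higher too, with 86.9%, 90.8% and 77.6% of their mutant counts in 1 cell each. Cluster 0 is a shallow class with medians of 1092 and 898 UMIs per cell, and 9 of the 10 genes that define it differed, so it may hold different cells in each library. Genes of the unfolded protein response were higher for 12 of 16 (median 0.54, percentile 100), with Hspa5 1.82-fold (1.63 to 2.03). Inflammatory cytokines were higher there for 7 of 9 (median 1.73, percentile 100). Glycolysis genes were lower for 11 of 14 (median -0.61, percentile 0), with Pgk1 2.51-fold (1.72 to 3.74).

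Outer enamel epithelium or stellate reticulum-like cells came from clusters 1 and 8, with all 495 control cells in cluster 1 and 75 mutant cells in cluster 1 beside 91 in cluster 8. Immediate early genes were lower in the mutant for 17 of 17 (median -1.31, percentile 0), with the stress factor Atf3, a leading gene of cluster 1, 27.6-fold lower (18.5 to 43.2) and Jun 5.15-fold lower (4.42 to 6.05). In cluster 1 alone the median was -2.83, and Atf3 was at 414 CPM in the control and 6.57 CPM (4 counts) in the mutant. In endothelium these were nearer to each other, at 145 CPM and 164 CPM for Atf3. Keratins and barrier genes were lower for 7 of 7 (median -0.87, percentile 0), with Krt17 2.30-fold lower (2.18 to 2.43), but in cluster 1 alone that median was -0.25. Cluster 8 was 3.95% of the mutant lineage and 0 of 2981 control lineage cells (0 to 0.124%). It met the rule for naming classes with 4 markers and a mean log2 fold of 1.20, though 0 of its 10 defining genes are markers of that type. They include Dcpp2, a secreted protein of salivary glands, at 630 CPM but seen in 8 of the 91 cells, and Col9a2 at 234 CPM. It shared Sfrp5 (768 CPM) with control cluster 1, which had 656 CPM, whereas mutant cluster 1 had 204 CPM. Krt14 was at 440 CPM in cluster 8, 1206 CPM in mutant cluster 1 and 1335 CPM in control cluster 1.

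**Figure D4:**
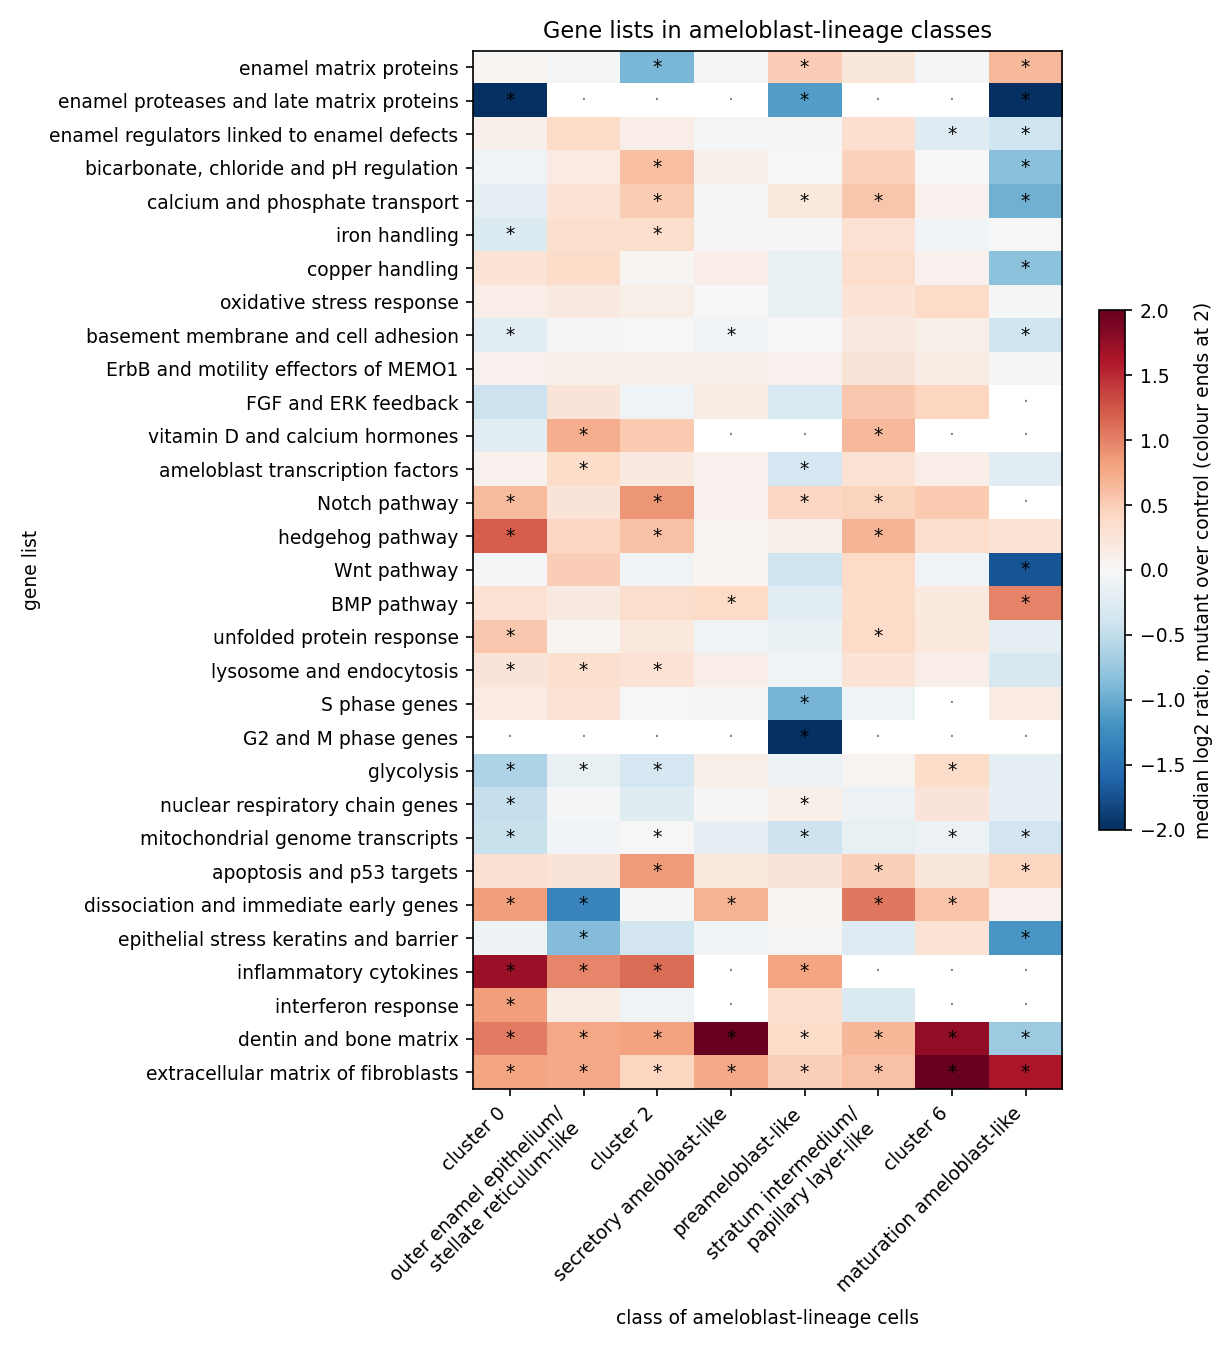
Median log2 ratios (mutant over control, colour ending at 2 each way) of gene lists in the 8 lineage classes, with a star where the median lies outside the central 95% of 10000 random lists of like expression and a dot where fewer than 3 members were measured. Fibroblast matrix genes are higher in all 8 classes, from 0.42 to 2.04, and late matrix genes of the maturation class are at -2.20.

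Genes of the extracellular matrix of fibroblasts were higher in the mutant in all 8 lineage classes, with medians from 0.42 in cluster 2 to 2.04 in cluster 6. In cluster 6 Col3a1 was 5.81-fold higher (4.53 to 7.57) and Lum 5.73-fold (4.47 to 7.45), and Sfrp2, a Wnt inhibitor of mesenchyme, 85.3-fold (49.7 to 161). Endothelium also had more Sfrp2 in the mutant, at 4.88 CPM and 172 CPM, and more Col3a1, at 27.2 CPM and 85.9 CPM. Changing the scaling to edgeR's TMM factors moved all log2 ratios by -0.26 in the stratum intermedium class, -0.24 in the outer enamel epithelium class, -0.23 in cluster 6, -0.21 in cluster 2 and -0.14 in secretory cells.

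Classes outside the lineage differed between the 2 libraries as well. Among 26 classes of any kind, Gm10709, a processed pseudogene, was named as lower in 25 and Gm8797 in 23, while Sfrp2 was named as higher in 12 and Erdr1 in 8. Over all cells Gm10709 had 389 CPM in the control and 1.55 CPM in the mutant. In fibroblast-like cells of cluster 7 Acta2, smooth muscle actin, was 10.3-fold higher (8.30 to 13), but 8 of the 10 genes that define this class differed, so it may hold different cells in each library. Pulp cells of cluster 5 had more Tnc (5.17-fold, 2.95 to 10.1) and Ogn (6.87-fold, 4.08 to 12.6), both matrix proteins. Macrophage or monocyte-like cells had more Cxcl1, a chemokine for neutrophils (2.67-fold, 2.52 to 2.83). Endothelial cells of cluster 15 had more Selp, an adhesion molecule of activated endothelium and a defining gene of that cluster (3.05-fold, 2.78 to 3.35).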

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

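The comparisons of list medians between classes were chosen after the medians had been seen, while the 3 tests of the maturation pattern were set down before their results were seen. The mice differ in sex as well as genotype. Xist, expressed from the inactive X of females, had 170307 counts in the mutant library and 49 in the control. Ddx3y of the Y chromosome had 5024 counts in the control and 5 in the mutant. Neither gene is part of the comparisons above, and sex cannot be separated from genotype anywhere in this study.

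Several gene groups went opposite ways in different classes of the lineage, and the differences between classes were not tested. Genes of bicarbonate, chloride and pH regulation had a median log2 ratio of -0.83 in the maturation ameloblast-like class and 0.61 in cluster 2. Calcium and phosphate transport stood at -0.96 in the maturation class and at 0.56 in the stratum intermedium or papillary layer-like class. Immediate early genes were at -1.31 in the outer enamel epithelium or stellate reticulum-like class and at 1.05 in the stratum intermedium class.

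The lower maturation markers within the maturation class were weighed against depth, mixing and stage. Mutant cells there had more UMIs (median 8059 against 5513). After thinning to 1000 UMIs the median log2 ratio of 6 markers was -2.65 against -3.53 before (146 control and 58 mutant cells kept, 41 and 20 left out). Thinning leaves a gene's expected share of a cell's counts unchanged, so this cannot decide depth. It shows only that the markers stayed lower when each kept cell counted equally. Secretory cells mixed into the mutant class would leave its true maturation cells with full Odam. Among cells with at least 5 Amtn UMIs after thinning (106 control and 17 mutant), the Odam ratio was 0.0242 (0.0104 to 0.0477). The mutant value rests on 8 Odam UMIs. These cells were not alike in Amtn either, with 24.75 UMIs per 1000 in the control and 11.65 in the mutant. The ratio therefore argues only against secretory cells mixed with maturation cells like those of the control, and does not cover a mix with cells of an earlier stage.

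An earlier stage of the mutant cells may explain part of it. Cells of the class had a median of 160 enamel matrix UMIs per 1000 in the control and 275.5 in the mutant. Across 722 genes, which are not independent, the mutant to control ratio followed the ratio of matrix-rich to matrix-poor control cells with a Spearman rho of 0.43, between the 0.1 and 0.5 set as limits, so stage stays open. Where along the incisor each sample was taken, sex and differences between single mice could not be tested and stay open too.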

How the results depend on the processing

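No paired analysis was possible because each group has 1 library. Taking cluster 1 alone was chosen after results had been seen. So were leaving out the top cell of each library and leaving out the mutant cell with the most Odam. The last of these left out no control cell, so larger Odam folds under it were largely fixed in advance. Named genes kept their direction for 340 of 340 under TMM factors, 160 of 160 under median-of-ratios factors and 160 of 160 with totals free of abundant transcripts. These genes were chosen for intervals far from 1. The largest shift of a log2 ratio was -0.26 under TMM and -0.27 under median-of-ratios factors, so kept directions under scaling were largely fixed by that choice. Named genes also kept their direction for 159 of 160 with stricter cell limits, means of per-cell CPM, no cells with the most UMIs, or no top cell, and for 157 of 159 after thinning, where En1 in the preameloblast class had too few counts left for a ratio. Sizes were less stable than directions. Apart from values that changed direction, the value left its main counting interval for 88 of 159 genes after thinning. It did so for 53 of 160 without the cells with the most UMIs and 13 of 20 in cluster 1 alone. Under TMM factors 22 of 91 list medians left theirs.

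The lineage share ratio (0.543) was 0.422 with stricter limits and 0.502 without the cells with the most UMIs. The ratio of maturation to secretory marker counts (0.0728) was 0.0635 and 0.0657 in these settings, and 0.0518 without the mutant cell with the most Odam. Of shares left uncompared in the report because leading genes differ, the ratio for cluster 6 in the lineage went from 1.48 to 0.826 without the cells with the most UMIs, and that of fibroblast-like cluster 21 from 1.60 to 0.736 with stricter limits.

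Among genes, Csn3 in the maturation class went from 30.3 to 0.494 without the cells with the most UMIs and Btbd3 from 5.76 to 0.839 after thinning. Cd14 in cluster 0 went from 5.30 to 0.793 with stricter limits, and S100a9 in the outer enamel epithelium class from 0.228 to 1.47 without the top cell. Mt1 in the preameloblast class went from 0.407 to 1.10 with per-cell means. Rnaset2a in cluster 6 went from 0.491 to 1.03 after thinning. Memo1 went from 0.693 to 0.407 in cluster 2 with stricter limits, and with per-cell means from 0.596 to 2.15 in the preameloblast class and from 1.21 to 0.495 in the maturation class.

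List medians kept their direction for 91 of 91 under TMM factors and 91 of 91 with members of at least 1 count. Means in the maturation class were -2.34 for late matrix proteins (median -2.20) and -0.25 for bicarbonate, chloride and pH regulation (median -0.83). Secretory immediate early genes (0.69) were at 0.55 with members of at least 50 CPM and 0.56 with TMM factors. In cluster 1 alone, immediate early genes went from -1.31 to -2.83, and 3 lists of that class reversed, vitamin D from 0.73 to -0.19, lysosome from 0.32 to -0.14 and haemoglobin from -0.90 to 0.42.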

Other observations

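The test of doublets with a pulp cell was chosen after the first doublet test had been seen, as were the bound on cells in the gland test and the use of quartiles for the free RNA tests. Beyond the epithelium, cells named odontoblast-like by the markers, after the cells that make dentin, had more dentin and bone matrix counts in the mutant (8 of 10 genes higher, median 0.72, percentile 100). Bglap and Dspp were nonetheless seen in fewer of the mutant cells. Bglap, osteocalcin and a leading gene of the class, was 4.80-fold higher (4.64 to 4.98) but seen in 30.9% of the control and 23.7% of the mutant cells, with 29.4% of the mutant counts in 1 cell. Dspp, the main dentin phosphoprotein gene, was 7.31-fold higher (6.29 to 8.53), at 57.9 CPM in the control and 423 CPM in the mutant. It was seen in 5.06% and 3.60% of cells, and 61.2% of its control and 37.7% of its mutant counts lay in 1 cell each. Few cells of the class thus carried this dentin gene. The bone gene Ibsp had 94.6% of its control and 77.5% of its mutant counts in 1 cell each, so these differences rest on few cells. Dlk1, a Notch ligand of immature mesenchyme, was 2.70-fold lower (2.37 to 3.08).

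Endothelial cells of cluster 15 were lower in the mutant for 15 of 15 genes of the G2 and M phases (median -1.75, percentile 0). They were higher for 10 of 11 inflammatory cytokines (median 1.40, percentile 100). Of the mutant counts, 73.4% of Il1b and 38.4% of Cxcl2 lay in 1 cell each. The macrophage marker C1qa was also higher (4.38-fold, 3.08 to 6.41), with 38.2% of its mutant counts in 1 cell. For these genes the difference rests partly on few cells. Pericyte or smooth muscle-like cells had more Actg2, a smooth muscle actin (4.51-fold, 3.66 to 5.61). Cycling cells had less Dkk1, a Wnt inhibitor (4.60-fold, 3.44 to 6.27), and less Smpd3, which is needed for mineralization (3.22-fold, 2.90 to 3.58). Cells of cluster 3 were lower for 16 of 17 immediate early genes (median -1.39, percentile 0), and those of cluster 11 higher for 14 of 17 (median 1.26, percentile 100).

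Cluster 8, with 91 mutant and 0 control lineage cells, was weighed as gland cells and as doublets. Its gland-like genes Dcpp2 and Scgb1c1 could come from a salivary or other gland taken with the tissue. Markers of gland cells summed to 3.02 CPM (0.624 to 8.83), under the 50 CPM set as a limit. That sum covers 3 of the 9 markers, since the other 6 are not in the file. The file has 452 genes seen in 3 cells and 54 seen in fewer, so genes seen in 2 or fewer cells seem to have been removed. If the missing markers were removed in that way, at most 15 of the 91 cells hold any of the 9, which argues against gland cells as the source of the whole cluster. A few gland cells within it stay open: Dcpp2 was seen in 8 of its cells and Scgb1c1 in 22. Doublets with a cell from outside the epithelium would carry its markers at 0.25 of their level or more. The highest fraction was 0.108, for pulp cells of cluster 5, just over the limit of 0.1 set for excluding doublets. A further test on the 10 leading pulp genes gave a median fraction of 0.0455 (0.0122 to 0.403, with 6 of 10 below 0.1). That range takes in the 0.25 set for doublets, and the test was chosen after the first had missed its limit, so doublets stay open. A state of outer enamel epithelium tied to the mutation, the sex or the dissection was not tested.

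The higher fibroblast matrix transcripts in mutant lineage classes might be RNA set free from damaged mesenchyme. Erythroid cells, which do not make them, had a median of 0.74 for the same list, a direction known when the tests were set down. In cluster 6, mutant cells held 6.06 times the UMIs of erythroid cells (median over 8 genes, quartiles 4.74 and 7.16), above the limit of 5 for excluding free RNA but with the lower quartile under it. In the maturation class the value was 2.2 (7 genes, quartiles 1.06 and 5.74), so free RNA cannot be told apart from expression in either class. No biological explanation was tested.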
